A study of Mus musculus with 6 samples.

How the data were processed

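Total RNA from passage 3 neurospheres was hybridised by the authors to Affymetrix mouse expression arrays after labelling from 500 ng of RNA, per the labels' protocols. The deposited table holds 1 column of log2 values per array for 45101 probe sets, and the submitters' processing notes name GCRMA, a background correction and quantile normalization of Affymetrix probes, with no version or settings. That the values are on a log2 scale was taken from their range of 1.22 to 15.58 and from their quantiles, which were nearly the same on all arrays (medians 4.01 to 4.04). Such a normalization gives every array about the same distribution, so a shift of most genes in 1 culture would not be visible. GCRMA also compresses values of weak probe sets towards a floor between about 2 and 4. Between 50.2% and 50.6% of the probe sets reached 4 on each array. Precision is limited by the number of arrays, 3 per group.

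Samples were grouped by their titles into rNCSC (3 arrays) and pNCSC (3 arrays), and all columns of the table were used. Probe sets were named through the platform annotation supplied with the data: 34958 had 1 gene symbol, 932 had several and were left out, and 9211 are unnamed here. A mouse RefSeq gene table (GRCm38.p6) was used for names only and changed 0 symbols. For each of 18194 genes the probe set with the highest mean over the 6 arrays was kept. Genes reaching a log2 value of 4 on fewer than 3 arrays were left out as dim (6472 genes), leaving 11722. Of 4157 changed genes with several bright probe sets, 212 had a probe set changed the opposite way.

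Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 without covariates, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. An exact permutation test of 3 against 3 arrays cannot give a p below 0.1. Differences are rNCSC minus pNCSC. Where a gene was under 4 on all arrays of a group, the fold is given as a lower bound, with arrays of that group below 4 set to 4. The same was done where only some arrays of the lower group were under 4, a rule added after the values had been seen and not used for the list medians with genes at their bound. The adjusted p of such a gene is that of the measured values. Gene lists (28, with at least 3 tested members each) were compared with camera at a preset correlation of 0.01, and again with a correlation estimated from the residuals, which have 4 degrees of freedom. fry was run on the same lists. It tests whether the genes of a list move one way on balance, and its mixed form whether they move in either direction. Neither compares a list with other genes. The lists covered CNS neural stem and progenitor, neural crest, Schwann cell, neuron, oligodendrocyte, astrocyte, Hox, craniofacial, mesenchymal, epithelial, leukocyte, endothelial and mural, melanocyte, muscle, bone, cell cycle, FGF, BMP, Notch, Wnt, Hedgehog, pluripotency, fetal growth, interferon, senescence, hypoxia and sex chromosome genes. Some genes stand on several lists.

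The design, the lists, the alternatives and the genes to be named were fixed before the data were examined. Named were the 10 genes with the largest difference in each direction (adjusted p under 0.05, no overlap between groups, clone names and predicted genes left out), the 4 genes in the labels, up to 3 members per direction of each list past the test (2 with the smallest p where none passed), and any member of the CNS, neural crest and Hox lists. Xist, Kdm5d and the other genes described as chosen after their values were seen fall outside that rule, as do the members named because a count of 5 or fewer was given. Alternatives covered the filter on dim genes (none, 3 or 6), the choice of probe set, quantile normalization and median centring of the arrays, a variance trend, a robust prior, array weights, the replicate number as a block, leaving out each array, every probe set tested, limma's treat, camera with an estimated correlation, fry and a floor of 3. Tested on simulated data with the same 11722 genes and spread as this comparison, the limma step recovered 1 of 67 genes changed by a log2 value of 0.5, 39 of 67 changed by 1 and 55 of 66 changed by 2, with 2 false calls among 11522 unchanged genes. Far fewer genes were changed there than the 73.3% called in the real fit, which makes the adjusted threshold stricter in the simulation. These recovery rates therefore do not carry over: the real fit called log2 differences down to 0.26.

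Some choices were revised after results had been seen. Reducing rNCSC to 1 array with the male pattern, and pNCSC to the array with few mast cell transcripts, were run once as added alternatives and dropped, because both pick arrays by measured values and leave 1 array in a group. In that run the counts of genes higher and lower in rNCSC moved strongly and the camera direction of the oligodendrocyte list turned, and no values from it are given here. Leaving out each array covers the same arrays singly. The test on normalization first used the median of all tested genes, which the normalization itself holds near 0, and was replaced by bacterial control transcripts, with its limit set after their values had been seen. The test on dividing cells was first run on members of the cell cycle list and then on genes of no list. The test of cultures of different sex first ran on the 4 genes that define the pattern, and was replaced by genes that escape X inactivation, named before their values were seen. Leaving out each array with the genes of the original fit kept was added after the planned fits had been seen. The test of mast cells for the leukocyte list was redefined, and that of macrophages was moved from 12 genes picked by hand to the whole list of 28.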

Results

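Genome-wide expression was measured on Affymetrix mouse arrays in neurospheres, free-floating spheres of dividing cells, grown from neural crest derivatives of C57BL/6J mice. The neural crest is the embryonic cell population that gives rise to the peripheral nervous system and to much of the mesenchyme of the face. The first group, called rNCSC, held 3 arrays of neurospheres from dorsal root ganglia, the sensory ganglia beside the spinal cord, taken at embryonic day 12.5. According to the labels these cells are reprogrammed in culture and can then form progeny of the central nervous system (CNS). The second group, called pNCSC, held 3 arrays of neurospheres from the palate of adult mice aged 6 to 8 weeks, with tissue taken from 3 to 5 mice, which the labels describe as not acquiring CNS progenitor markers. Both were grown with fibroblast growth factor, EGF and heparin and were sampled at passage 3. The question was how the 2 cultures differ in gene expression. Tissue, age of the donors and culture type change together between the groups, and the labels give 2 levels of fibroblast growth factor (20 or 40 ng/ml) and of the B27 supplement (1% or 3%) without saying which culture received which. No uncultured tissue is in the series, so levels in the 2 cultures are compared and no induction or loss over time. Nothing in the labels says whether the 3 arrays of a group came from separate cultures or animals, or whether the 3 to 5 mice were pooled for each, so p-values measure only the spread between these samples.

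Of 11722 genes tested, 8596 (73.3%) differed between the cultures (limma, Benjamini-Hochberg adjusted p under 0.05), 4717 with higher and 3879 with lower values in rNCSC. By measured values, at least 2-fold differences were found for 5566 genes, 2865 higher and 2701 lower in rNCSC, and at least 16-fold differences for 453 and 685 genes. Of the changed genes, 986 lay under 4 on all rNCSC arrays and 676 on all pNCSC arrays. With such arrays set to 4, some of these genes need not reach the folds counted. In 9168 genes (78.2%) the values of the groups did not overlap, against 10% given by chance with 3 against 3 arrays. Arrays of the same group correlated at r = 0.988 to 0.996 over all probe sets, and arrays of different groups at 0.833 to 0.844. The first principal component, which separated the groups, held 94.6% of the variance, and the second held 2.25% and set pNCSC replicate 1 apart from pNCSC replicates 2 and 3. The median SD of a tested gene was 0.16 in rNCSC and 0.19 in pNCSC on the log2 scale.

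By measured difference, values under 4 included, the 10 genes furthest towards rNCSC were Gpm6a (a neuronal membrane glycoprotein), Zic1, Olig1, Bcan, Olig2, Ptprz1, Fabp7, Ncan, Bex1 and Grm5. Gpm6a had a log2 value of 14.53 ± 0.09 (SD, n = 3) in rNCSC and 2.35 ± 0.09 in pNCSC, at least 1483-fold higher, with all means below given in the same way. Bcan and Ncan encode brain proteoglycans, and were at least 530-fold and at least 287-fold higher. The glutamate receptor gene Grm5 was at least 257-fold higher. Furthest towards pNCSC stood Dmp1 (a mineralised matrix protein), Rgs5, Mmp3, Col3a1, Apod, Mmp13, S100a8, Lcn2, Mgp and Fabp4. Dmp1 was at 14.77 ± 0.20 in pNCSC and 2.79 ± 0.13 in rNCSC, at least 1751-fold higher in pNCSC. The matrix metalloproteinase gene Mmp3 was at least 2033-fold and the iron-sequestering lipocalin gene Lcn2 at least 1912-fold higher in pNCSC. The adjusted p of these 20 genes was 1.8e-06 or lower. Where a gene lay under a log2 value of 4 on some or all arrays of the lower group, the fold is a lower bound, with those arrays set to 4. By these bounds the order would differ, as Mest, named below, has a larger bound than Bcan, Zic1 and 4 others of the first 10, and Clu a larger one than Apod, Fabp4 and Mmp13.

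Among the genes named in the labels, Olig2, a transcription factor of oligodendrocyte and motor neuron progenitors, was at 12.75 ± 0.14 in rNCSC and 2.43 ± 0.18 in pNCSC (at least 431-fold, limma adjusted p = 3.0e-08). Cnp, the gene of the myelin enzyme CNPase, was 3.91-fold higher in rNCSC (log2 difference 1.97, SE 0.19, adjusted p = 0.00011). The peripheral glia and neural crest genes were the reverse. Ngfr, which encodes the p75 receptor, was under 4 on all 3 rNCSC arrays and at 7.52 ± 1.18 in pNCSC (at least 11.5-fold higher, adjusted p = 0.00059), with pNCSC values from 6.22 to 8.55. Sox10 was also under 4 on all rNCSC arrays and at 4.93 ± 0.50 in pNCSC, at least 1.90-fold higher (adjusted p = 0.0055). The other probe sets of Sox10 and of Ngfr had group means under 4 in both cultures.

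The list of CNS neural stem and progenitor genes was higher in rNCSC for 24 of 25 tested members, and 14 of the 25 lay under 4 on every pNCSC array. Sox1, Sox3 and Pax6, transcription factors of the early neural tube, were at least 22.7-fold, at least 74.2-fold and at least 32.8-fold higher in rNCSC. Fabp7, a fatty acid binding protein of radial glia, was 862-fold higher and the ciliogenic factor gene Rfx4 at least 167-fold higher. Several members were well above 4 in pNCSC too: Sox2 was at 13.64 ± 0.14 in rNCSC and 9.92 ± 0.36 in pNCSC, a 13.2-fold difference (adjusted p = 6.8e-06). Nes stood at 6.21 ± 0.33, Pou3f3 at 6.80 ± 0.35, Slc1a3 at 7.40 ± 0.27 and Egfr at 7.33 ± 0.52 in pNCSC, each between 11.8-fold and 66.6-fold below rNCSC. The exception was Irx3, 2.87-fold higher in pNCSC (adjusted p = 0.00093). The median log2 difference of the list was 5.72, or 4.84 with genes at their bound (camera adjusted p = 2.1e-08; adjusted p = 0.13 with an estimated correlation). Of the 40 members, 13 were too dim to test. Among members that mark single brain or neural tube regions, grouped after their values were seen, Lhx2 was at least 6.17-fold higher in rNCSC (adjusted p = 0.00063) and Nkx2-2 at least 2.39-fold (adjusted p = 0.018, lost without pNCSC replicate 3 at 0.052), Emx2, Dbx2 and Nkx6-1 reached 4 on 1 or 2 rNCSC arrays, and Otx1, Otx2, Gsx1, Gsx2, Dbx1 and Nkx6-2 were under 4 on all 6 arrays. Nkx2-2 was at 7.27 on rNCSC replicate 1 but only at 4.05 and 4.44 on rNCSC replicates 2 and 3. It left the test when any rNCSC array was left out.

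**Figure D1:**
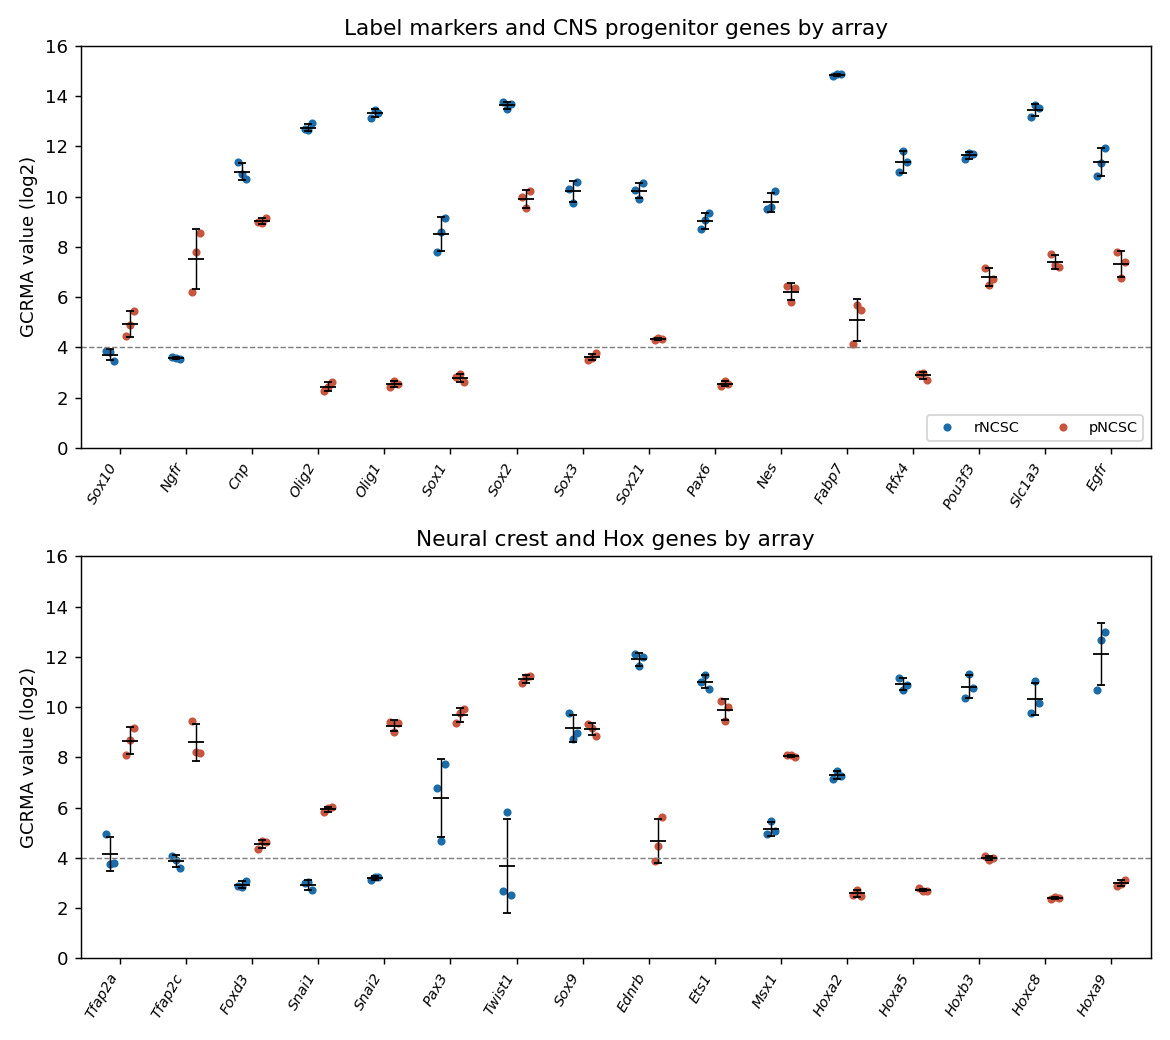
GCRMA log2 value (vertical axis) of the label markers and CNS progenitor genes (upper panel) and of neural crest and Hox genes (lower panel) on the 3 rNCSC arrays (blue) and 3 pNCSC arrays (red). Points are arrays, bars the mean ± SD and the dashed line the filter level of 4: Olig2 separates the groups (12.75 and 2.43), Sox2 is above 4 in both, and Sox9 is alike (9.16 and 9.12).

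Of 27 tested neural crest genes, 17 were higher in pNCSC, 5 in rNCSC and 5 did not pass the test. Tfap2a and Tfap2c, early crest transcription factors, were at least 20.4-fold and higher by a log2 value of at least 4.59 in pNCSC, Snai2 at least 38.3-fold and Foxd3, at 4.55 ± 0.16 there, at least 1.46-fold. The retinoic acid binding protein gene Crabp1 was at least 250-fold higher in pNCSC (12.90 ± 0.48 against 4.93 ± 1.43). The 5 genes higher in rNCSC were Ednrb (at least 148-fold), Myc, Cdh6, Id2 and Ets1. Sox9 had a log2 difference of 0.04 (SE 0.28) and Sox5 of -0.04 (SE 0.25), and neither passed the test, nor did Lmo4, Nr2f1 and Itga4, though Nr2f1 was called higher in rNCSC under 5 alternatives and Itga4 without rNCSC replicate 2. The list median was -1.73, or -1.15 with genes at their bound (camera adjusted p = 0.0098; adjusted p = 0.22 with an estimated correlation). The call was also lost with the filter at 6 (adjusted p = 0.099) and without pNCSC replicate 1, 2 or 3, at adjusted p = 0.28, 0.20 and 0.30. The list mean was -1.77, and between -1.10 and -0.99 without a pNCSC array. In a fit without 1 array the filter still asks for 3 arrays, so genes above 4 only in the culture that lost the array leave the test, here and below. With the genes of the original fit kept, an alternative chosen after seeing the data, this call held in all 6 such fits (adjusted p from 0.0048 to 0.013).

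Glial and neuronal lists had members on both sides. Among 20 Schwann cell genes, 10 were higher in pNCSC, among them the myelin-associated gene Ncmap (by a log2 value of at least 3.33) and the neuregulin receptor gene Erbb3 (at least 4.95-fold), and 6 in rNCSC, led by Fabp7 and Pou3f1 (at least 17.1-fold). Among 18 sensory and autonomic neuron genes, 9 were higher in rNCSC, with the RNA-binding protein gene Elavl4 at least 94.2-fold and Neurod1 at least 13.5-fold higher, and 4 in pNCSC: Runx1 (at least 88.7-fold), Snap25 (15.7-fold), Tac1 and Runx3, the last chosen after its values were seen. The Tac1 call was lost without rNCSC replicate 2 or 3 (adjusted p = 0.051 and 0.060). Of 30 astrocyte and radial glia genes, 15 were higher in rNCSC, including the Notch target Hes5 and Mlc1 (at least 68.7-fold and 74.6-fold), and 9 in pNCSC, including Clu, at 14.76 ± 0.18 against 4.43 ± 0.74. None of these 3 lists was called (camera adjusted p = 0.42, 0.56 and 0.39). Oligodendrocyte lineage genes were higher in rNCSC for 10 of 15 members, with Olig1 at least 637-fold and Cntn1 at least 297-fold higher, while Pdgfra (28.2-fold), Sox10 and Aspa (2.01-fold) were higher in pNCSC. That list had a median of 2.78, or 1.97 with genes at their bound (camera adjusted p = 0.046; adjusted p = 0.25 with an estimated correlation), and the call was lost when any 1 of the 6 arrays was left out, at adjusted p from 0.058 to 0.60, with the mean at 0.74 to 1.10 without an rNCSC array and 3.59 to 3.64 without a pNCSC array, against 3.30. With the genes of the original fit kept it was lost without pNCSC replicate 1 or 3 (adjusted p = 0.066 and 0.058). It was lost without the filter too (mean 1.80, adjusted p = 0.088).

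Positional genes separated the cultures. Hox genes, which mark position along the body axis, were higher in rNCSC for 8 of 9 tested anterior members (paralogues 1 to 5) and for all 9 tested posterior members (paralogues 6 to 13). Hoxa5 was at 10.90 ± 0.24 in rNCSC and 2.72 ± 0.05 in pNCSC (at least 120-fold), Hoxc8 was at least 80.2-fold and Hoxa9 at least 278-fold higher. Hoxa3 was the exception, 1.75-fold higher in pNCSC (adjusted p = 0.0011), but another probe set of the gene went the opposite way and the mean of its probe sets was higher in rNCSC. The medians were 3.86 for the anterior list (2.69 with genes at their bound, camera adjusted p = 0.0054) and 4.61 for the posterior list (4.31 with genes at their bound, camera adjusted p = 0.0015), with 4 of 15 and 11 of 24 members too dim to test and with adjusted p = 0.28 and adjusted p = 0.22 with an estimated correlation. Without the filter the mean difference of the posterior list fell from 5.46 to 2.82 and its call was kept (adjusted p = 0.010). The anterior call was also lost without rNCSC replicate 1, 2 or 3 (adjusted p = 0.31, 0.35 and 0.39), and held in all 6 fits with the original genes kept. Of 29 craniofacial and palate patterning genes, 26 were higher in pNCSC, among them Twist1 (at least 91.0-fold), Tbx3 (at least 72.0-fold), Tbx2 (at least 45.6-fold) and Msx1 (7.56-fold). Meis2 and Foxp2 were higher in rNCSC, 1.73-fold and at least 1.39-fold, Meox2 did not pass the test, and the calls of Meis2 and Foxp2 were lost without 1 array (Meis2 without rNCSC replicate 3 or pNCSC replicate 3, Foxp2 without rNCSC replicate 1 or 3 or pNCSC replicate 2 or 3, at adjusted p from 0.056 to 0.12). The Foxp2 call was also lost without the filter (adjusted p = 0.058) and with the filter at 3 (0.051). The craniofacial median was -3.68, or -3.30 with genes at their bound (camera adjusted p = 1.6e-07; adjusted p = 0.12 with an estimated correlation).

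Mesenchymal and fibroblast genes were higher in pNCSC for 35 of 36 tested members, the remaining gene, Fbln1, not passing the test. Fibrillar collagen Col3a1 was at 14.46 ± 0.03 in pNCSC and 2.89 ± 0.28 in rNCSC (at least 1411-fold), the growth factor receptor gene Pdgfrb at least 555-fold and decorin (Dcn) at least 839-fold higher. The list median was -7.99, or -7.57 with genes at their bound (camera adjusted p = 6.7e-14; adjusted p = 0.12 with an estimated correlation). Endothelial and mural genes were higher in pNCSC for 7 of 9 tested members, led by the pericyte-associated genes Rgs5 (at least 1284-fold), Abcc9 (at least 218-fold) and Kcnj8 (at least 146-fold), while 16 members were too dim to test. The median was -2.45 (camera adjusted p = 0.0028; adjusted p = 0.13 with an estimated correlation), and the call was lost without pNCSC replicate 1, 2 or 3 (adjusted p = 0.14, 0.15 and 0.095), where the mean fell from -4.30 to between -1.15 and -0.96. With the original genes kept the call held in all 6 fits (means from -4.38 to -4.20). Without the filter its mean was -1.63 and the call was kept (adjusted p = 0.010).

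Markers of other cell types of the source tissues were mostly dim. Of 35 epithelial and keratinocyte genes, 23 were too dim to test, 7 were higher in pNCSC (Perp at least 24.9-fold, Ivl at least 3.63-fold, Krt18 at least 2.78-fold) and Lor was higher in rNCSC by a log2 value of at least 1.32 (camera adjusted p = 0.060). The Krt18 call was lost without rNCSC replicate 3 (adjusted p = 0.053). The list was called without the filter (mean -0.63 against -1.36, adjusted p = 0.0087), with the filter at 3 (0.017) and with array weights (0.039). Of 28 macrophage and leukocyte genes, 20 were too dim to test and 7 of the other 8 were higher in pNCSC, with Cd14 at 9.87 ± 1.14 (at least 58.6-fold), Trem2 at 8.38 ± 0.70 (at least 20.8-fold) and Cd53 at 8.08 ± 0.96 (at least 16.9-fold). The leukocyte median was -3.32, or -2.59 with genes at their bound (camera adjusted p = 0.0087; adjusted p = 0.22 with an estimated correlation), and without the filter the mean went from -3.30 to -1.11 with the call kept (adjusted p = 0.012). The leukocyte call was lost on probe sets without _s_at, _x_at or _a_at endings (adjusted p = 0.055). Without a pNCSC array the few members left had a mean between -1.09 and -0.38. Mast cell genes, chosen after their values were seen, differed among pNCSC arrays beside this list: Cpa3 was at 6.45, 10.53 and 11.82 on replicates 1, 2 and 3. Melanocyte genes (4 tested, camera adjusted p = 0.65), skeletal muscle genes (5 tested, camera adjusted p = 0.12) and bone and cartilage genes (10 tested, camera adjusted p = 0.55) were not called, and the bone mean of -1.39 turned to between 1.28 and 1.47 without a pNCSC array, but stayed between -1.43 and -1.33 with the original genes kept. Muscle genes were called without the filter (mean -0.60 against -1.43, adjusted p = 0.024) and with the filter at 3 (0.034). Among these lists Mitf was 7.47-fold, Myl1 at least 5.10-fold and Ibsp at least 5.75-fold higher in pNCSC, and Sox6 20.2-fold higher in rNCSC. Dmp1, the gene furthest towards pNCSC by measured difference, also stands on the bone and cartilage list (at least 1751-fold). It was above 4 on pNCSC arrays only, so it left the test without a pNCSC array. Of the 10 tested bone and cartilage genes, 4 were higher in rNCSC, 4 in pNCSC and 2 did not pass the test.

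Cell cycle genes were higher in rNCSC for 36 of 37 members, the exception being E2f1, which did not pass the test. The mitotic kinase gene Bub1 was at 11.68 ± 0.10 in rNCSC and 5.09 ± 0.60 in pNCSC, a 96.1-fold difference (adjusted p = 2.7e-06). The spindle motor genes Kif11 and Cenpe were 90.8-fold and at least 89.2-fold higher. The median log2 difference was 4.88 (camera adjusted p = 1.6e-12; adjusted p = 0.22 with an estimated correlation). Senescence and p53 genes were higher in pNCSC for 15 of 20 members. Mmp3 and the chemokine genes Cxcl1 (at least 501-fold) and Ccl2 (at least 348-fold), secreted factors, led the list, and Sesn1 (3.22-fold), the cyclin-dependent kinase inhibitor gene Cdkn2c (2.38-fold) and Plk2 (1.78-fold) were higher in rNCSC, with the Plk2 call lost without rNCSC replicate 2 (adjusted p = 0.053). The median was -2.95, or -2.92 with genes at their bound (camera adjusted p = 0.00026; adjusted p = 0.13 with an estimated correlation).

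**Figure D2:**
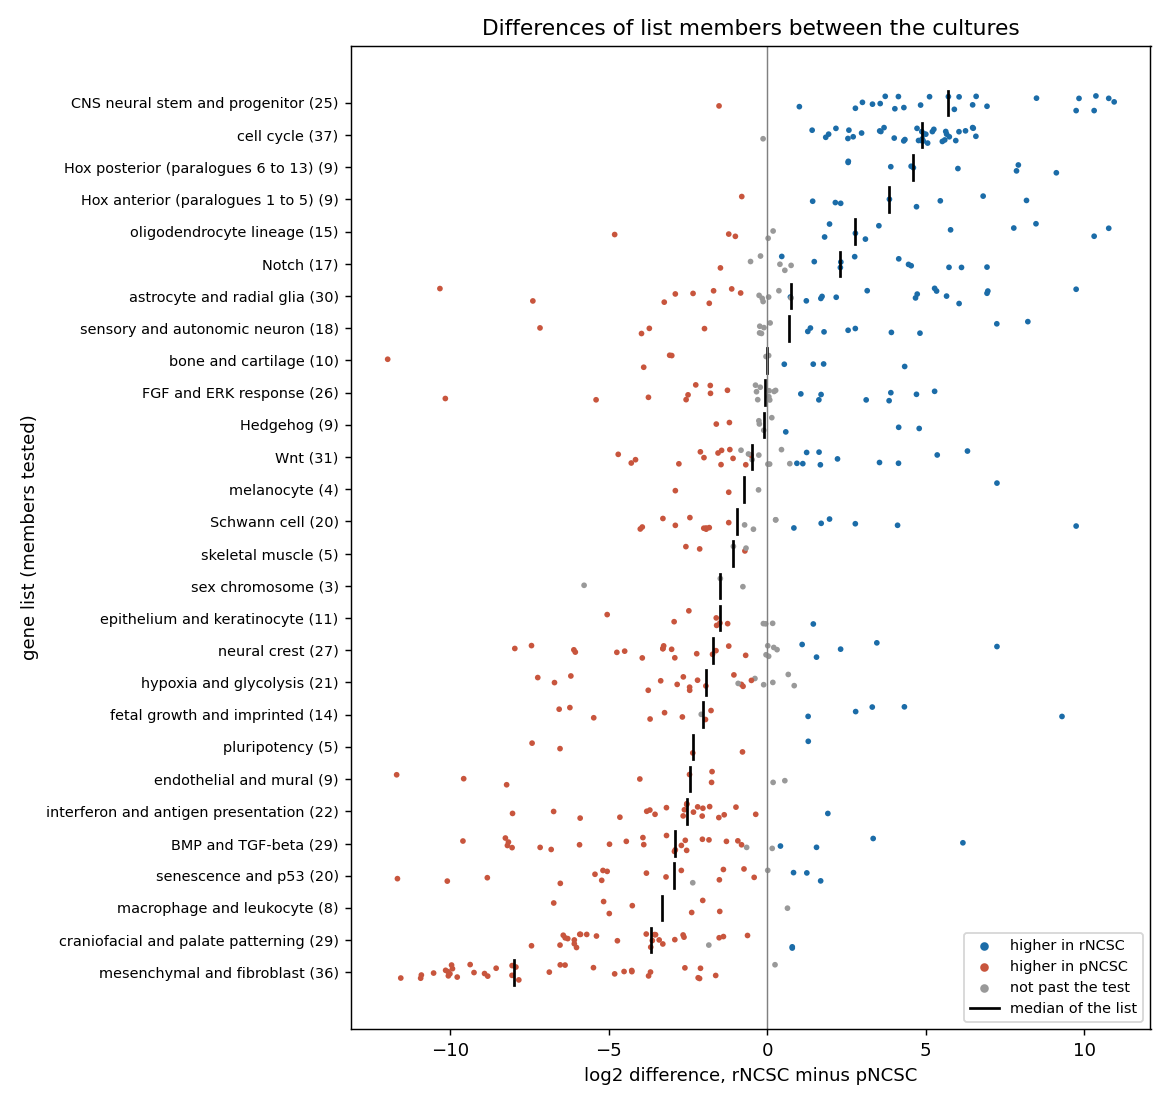
Log2 difference between rNCSC and pNCSC (horizontal axis, positive where rNCSC is higher) of each tested member of the 28 gene lists, 1 row per list with the number of tested members in brackets. Blue and red points passed the test in favour of rNCSC and pNCSC, grey points did not, and list medians (black bars) run from -7.99 for mesenchymal and fibroblast genes to 5.72 for CNS progenitor genes.

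Interferon and antigen presentation genes were higher in pNCSC for 21 of 22 members, with Ifi35 at least 128-fold, the guanylate-binding protein gene Gbp2 at least 42.2-fold and the class I antigen gene H2-D1 higher by a log2 value of 5.91, and with Ifit2 3.77-fold higher in rNCSC (median -2.54, or -2.05 with genes at their bound, camera adjusted p = 6.1e-07; adjusted p = 0.22 with an estimated correlation). Hypoxia and glycolysis genes were higher in pNCSC for 15 of 21 members and did not pass the test for 6. The collagen hydroxylase gene P4ha2 was at least 106-fold, Pfkp at least 91.4-fold and Car9 at least 28.1-fold higher, and Car9 ranged from 7.02 to 10.88 over the pNCSC arrays (median -1.94, camera adjusted p = 0.00049; adjusted p = 0.36 with an estimated correlation). Pluripotency genes were mostly dim. Of 5 tested, Klf4 (172-fold), Tbx3, Klf2 (at least 4.77-fold) and Klf5, the last chosen after its values were seen, were higher in pNCSC and Esrrb at least 1.35-fold higher in rNCSC (camera adjusted p = 0.060, and called without rNCSC replicate 1, 2 or 3, at adjusted p = 0.015, 0.017 and 0.020, and with the mean of the probe sets at 0.024). Without the filter the pluripotency mean went from -3.16 to -0.69 (adjusted p = 0.67). Fetal growth and imprinted genes went both ways (camera adjusted p = 0.21), with the paternally expressed gene Mest at least 582-fold and Igf2bp3 at least 11.3-fold higher in rNCSC, and the maternally expressed RNAs Meg3 (at least 78.5-fold) and Rian (at least 40.2-fold) higher in pNCSC.

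Among signalling lists, 23 of 29 BMP and TGF-beta genes were higher in pNCSC, with Bmp2 at 13.68 ± 0.09 against 4.07 ± 0.41 (at least 718-fold), Inhba at least 198-fold and Tgfbr3 at least 290-fold higher. The 4 members higher in rNCSC were Bmpr1b (at least 25.3-fold), Bmp7 (at least 5.02-fold), Id2 (2.94-fold) and Bmpr1a, the last chosen after its values were seen (list median -2.90, or -2.71 with genes at their bound, camera adjusted p = 3.4e-05; adjusted p = 0.13 with an estimated correlation). Notch genes were higher in rNCSC for 11 of 17 members, with the ligand-like gene Dner 70.2-fold and the Notch target Nrarp at least 35.7-fold higher, and only Notch2 was higher in pNCSC (2.79-fold). Their median was 2.31 (camera adjusted p = 0.0054; adjusted p = 0.22 with an estimated correlation), and the call was lost without rNCSC replicate 2 (adjusted p = 0.058) but held with the original genes kept. The lists of FGF and ERK response, Wnt and Hedgehog genes were not called (camera adjusted p = 0.55, 0.55 and 0.94). In these, Fgfr3 (39.0-fold), Lgr5 (at least 35.1-fold) and Ptch1 (17.7-fold) were higher in rNCSC, and Fgf7 (at least 760-fold), Dkk3 (at least 25.2-fold) and Gas1 (3.05-fold) in pNCSC. Median and mean differ in sign for the Hedgehog list (-0.11 and 0.69), the melanocyte list (-0.74 and 0.72) and the bone and cartilage list (0.0035 and -1.39). For Wnt, Hedgehog and melanocyte genes camera pointed to pNCSC and fry to rNCSC, with Wnt at a median of -0.48. In all, 15 of the 28 lists were called, 0 of them with an estimated correlation (camera, 6 lists at an unadjusted p under 0.05). Correlated members do not account for every such loss. The endothelial and mural list had an estimated correlation of -0.088, and its unadjusted camera p still rose from 0.0010 to 0.027. Counts adjusted over the list alone equalled those over all genes except for neural crest (6 higher in rNCSC), leukocyte (1 higher in rNCSC) and Hedgehog genes (2 higher in rNCSC).

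The arrays within rNCSC differed in sex-linked genes and in Hox genes of paralogue groups 9 and 10. Xist, the RNA that silences an X chromosome in female cells, was at 11.38 on rNCSC replicate 1 and between 2.73 and 3.12 on the 5 other arrays. The Y-linked genes Kdm5d and Uty were at 1.61 and 1.73 on rNCSC replicate 1, and at 6.76 or above on every other array. Eif2s3y, also Y-linked, was at 11.67 on rNCSC replicate 2 and between 11.01 and 11.37 on the pNCSC arrays, but at 2.25 on rNCSC replicate 3. None of the 3 tested genes of this list passed the test (limma adjusted p = 0.068, 0.72 and 0.49 for Eif2s3y, Kdm5d and Uty), and without rNCSC replicate 1 Uty was called higher in rNCSC, while Eif2s3y was called higher in pNCSC without rNCSC replicate 2 and, with all arrays kept, under array weights (log2 difference -6.75, adjusted p = 0.012). Hoxc10 was at 2.51, 9.11 and 5.32 and Hoxd10 at 2.36, 8.99 and 2.33 on rNCSC replicates 1, 2 and 3, with all pNCSC values under 4. Hoxd9 was called at least 3.78-fold higher in rNCSC (adjusted p = 0.047), a call lost without pNCSC replicate 1, 2 or 3 (adjusted p = 0.099, 0.10 and 0.10) and, with all arrays kept, without the filter (0.068), with the filter at 3 (0.059), under quantile normalization (0.051) and with a robust prior (0.052).

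**Figure D3:**
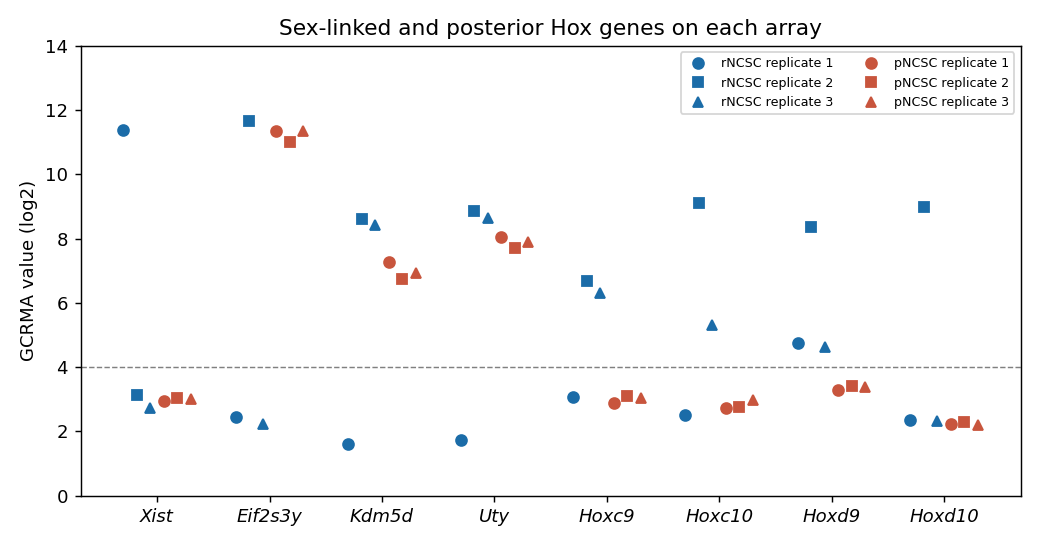
GCRMA log2 value (vertical axis) of 4 sex-linked and 4 posterior Hox genes on each array, with rNCSC in blue, pNCSC in red and a marker shape per replicate number. Xist is above 4 (dashed line) on rNCSC replicate 1 alone, and Hoxd10 on rNCSC replicate 2 alone (8.99).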

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

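These alternatives were planned, except leaving out each array with the genes of the original fit kept, chosen after seeing the data, and 2 others were run and dropped, as described for the processing. The number of changed genes lay between 6761 (filter at 6) and 9728 (no filter) over the alternatives that keep all arrays and 1 value per gene, against 8596, and between 6928 and 7597 when 1 array was left out. Testing every probe set gave 17897 calls, since more features enter. Genes changed at least 2-fold numbered 3892 with treat and 4624 to 5054 without 1 array, against 5566. Under quantile normalization and median centring 54.4% of the changed genes were higher in rNCSC, against 54.9%, but 61.3% to 62.6% without a pNCSC array and 50.1% to 51.2% without an rNCSC array. With the genes of the original fit kept, this share was 54.3% to 55.2% in the 6 fits without 1 array. Under the scalings 1 median of a list or family, that of bone and cartilage genes (0.0035), changed sign. The deposited values were already normalized, with array medians of 4.01 to 4.04, so quantile normalization and median centring could change little. Their agreement is therefore no check on the normalization itself. The replicate number as a block gave 8166 changed genes, and the deviations of same-numbered arrays correlated at 0.047, -0.029 and -0.038. No strong shift shared by same-numbered arrays is seen, but this cannot exclude a shared day or batch, on which the labels are silent. Of 28 lists 15 were called, 11 to 13 without 1 array, 22 with fry, and 0 by camera with an estimated correlation (6 at an unadjusted p under 0.05). Of the 15 called lists, 8 kept their call in all 6 fits that left out 1 array. The posterior Hox list kept it without each pNCSC array and the leukocyte list without each rNCSC array, and neither could be tested in the other 3 fits, where under 3 members were left. The neural crest, oligodendrocyte, anterior Hox, endothelial and Notch lists lost it in some. The filter then asks for 3 of 5 arrays, so members seen only in the culture that lost an array drop out, and the means of 6 lists not called (Schwann, sensory and autonomic neuron, epithelium, bone, FGF and Wnt) turned sign in some of these fits. With the original genes kept, the 6 fits gave 7903 to 8618 changed genes, 5472 to 5632 changed at least 2-fold and 14 or 15 lists, 14 of the 15 lists held in all 6, the oligodendrocyte list was lost without pNCSC replicate 1 or 3, and the epithelial list was called without pNCSC replicate 1 (adjusted p = 0.027). The neural crest call also ended with the filter at 6, the oligodendrocyte call without a filter or with the filter at 3, and the leukocyte call on probe sets without _s_at, _x_at or _a_at endings (adjusted p = 0.055). Of 2674 comparisons of 197 named genes with the original fit, 2637 kept their side of the threshold (10 of them past it in neither fit and of opposite sign), 27 lost and 8 gained the call, and 2 turned: Hoxa3 had a log2 difference of 0.70 with the mean of its probe sets, and Uty ran from -2.70 to 0.86 when 1 array was left out, turning without rNCSC replicate 1. Why the other results changed was not tested. A named gene that left the test in a fit was not compared there, as with genes above 4 only in the culture that lost an array. Named genes that kept their side numbered 118 to 122 without a pNCSC array and 128 to 131 without an rNCSC array, against 175 with array weights. The count of 2637 therefore does not cover the genes that dropped out. A floor of 3 raised the bounded folds by 0.22 to 1.00 on the log2 scale.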

Other observations

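The families in this paragraph and their members were chosen after the data were seen, 20 families were tested with camera, and the symbol patterns of 3 (integrins, complex I and ribosomal proteins) were tightened after a first run had caught genes that are not members. All 11 tested cathepsin genes, which encode lysosomal proteases, were higher in pNCSC, with Ctsk at 12.51 ± 0.34 (SD, n = 3) against 3.54 ± 0.14 (limma adjusted p = 1.3e-07; family camera adjusted p = 0.00011; adjusted p = 0.13 with an estimated correlation). Chemokine genes were higher in pNCSC for 14 of 16 members (median -5.44, or -4.43 with genes at their bound, camera adjusted p = 4.2e-05; adjusted p = 0.13 with an estimated correlation), including Cxcl5 at 11.97 against 2.34. Matrix metalloproteinase genes were higher in pNCSC for 13 of 15 (median -7.16, or -6.57 with genes at their bound, camera adjusted p = 2.6e-05; adjusted p = 0.22 with an estimated correlation), and some of their members also stand on the mesenchymal and senescence lists. In the other direction, 14 of 15 sterol synthesis genes were higher in rNCSC, with smaller differences (median 1.27, camera adjusted p = 0.0021; adjusted p = 0.53 with an estimated correlation), led by Dhcr7 at 8.74 ± 0.52 against 5.97 ± 0.19. Splicing factor genes of the SR and hnRNP families were higher in rNCSC for 25 of 29 (median 0.95, camera adjusted p = 5.4e-05; adjusted p = 0.13 with an estimated correlation), and respiratory complex I genes for 24 of 34 (median 0.64, camera adjusted p = 0.0030; adjusted p = 0.56 with an estimated correlation). Ribosomal protein genes did not pass the test for 30 of 38.

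S100a8 and Lcn2, genes of abundant neutrophil proteins that are also induced in other cells, were at 14.27 ± 0.13 and 14.90 ± 0.40 in pNCSC. The cyclin-dependent kinase inhibitor genes Cdkn2a and Cdkn2b, chosen after their values were seen, were at 11.93 ± 0.32 and 12.33 ± 0.16 in pNCSC against 6.49 ± 0.96 and 5.80 ± 0.34 in rNCSC (limma adjusted p = 5.9e-05 and 5.5e-07).

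The tests in the next 3 paragraphs were chosen after the result was seen, except those on further cell cycle genes, genes that escape X inactivation and further mast cell genes, whose values had not been seen. The first pattern is the lower level of cell cycle genes in pNCSC (list median 4.88 higher in rNCSC). Array normalization as the whole cause would also move bacterial control transcripts, usually added in equal amounts, and the largest shift among 40 probe sets was 0.70, towards pNCSC (largest SD in a group 0.77), which bears on levels per RNA amount and not per cell. RNA degradation would widen the 3' to 5' difference of control probe sets, and the larger shift of Actb and Gapdh was 0.15, while pyruvate carboxylase shifted by 1.32 with a 5' probe set near the floor (4.48 in pNCSC) and 18S rRNA by -0.93. A hypothesis is that fewer cells divide in pNCSC: among genes on none of the lists, 22 of 23 DNA replication genes and 24 of 25 mitosis genes were higher in rNCSC, and the smaller of the medians was 3.74, so the levels are consistent with it. The result of the cell cycle list was known when these genes were picked, and they rise and fall with its members, so this is not independent evidence, and donor age, tissue and medium stay open as untested.

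The second pattern is the difference in sex-linked genes among rNCSC arrays. Cells of both sexes on each array are argued against, since Xist and a Y-linked gene were both at 4 or above on 0 of the 3 arrays. Cultures of different sex on replicates 1 and 2 are a candidate explanation: of the genes Kdm5c, Kdm6a, Eif2s3x and Ddx3x, which escape X inactivation and are outside the pattern, 4 of 4 were higher on replicate 1 than on replicates 2 and 3, as a second X chromosome predicts. For Eif2s3y on replicate 3, a failed probe set and a missing transcript cannot be told apart, because the further probe set of the gene reached only 3.70 even on replicate 2. If the arrays hold different cultures, their differing Hoxc10 and Hoxd10 levels may reflect ganglia of different axial level, which was not tested. The differences were not confined to these genes. Emx2 (2.62, 6.11 and 4.97 on replicates 1, 2 and 3) and En2 (3.84, 9.42 and 7.17), the latter chosen after its values were seen, were also lowest on replicate 1. Hoxa7 was highest there (8.53, 6.34 and 7.31).

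The third pattern is the mast cell and leukocyte genes in pNCSC. Cma1 was at 4.42, 7.68 and 9.88 and Fcer1a at 3.55, 6.82 and 8.91 on replicates 1, 2 and 3. Mast cells on replicates 2 and 3 remain possible: of 15 further mast cell genes 9 reached 4 there, and 3 of these (Tpsb2, Hdc and Srgn) were higher by 1 or more on both arrays than on replicate 1, too few to bear it out and too many to set it aside. Near the floor, where values are compressed, a step of 1 is hard to reach, so this count may be too low. Tpsab1, at 3.30, 3.95 and 5.07 on replicates 1, 2 and 3, missed it on replicate 2, whereas Rab27b, at 4.90, 4.45 and 5.13, was not higher on replicate 2. Mast cells on replicates 2 and 3 do not account for the leukocyte list, of whose 7 called genes 1 (Laptm5) was higher by 1 or more on both arrays. Macrophages are argued against as its source, since 17 of the 28 members, with the abundant C1qa (2.39), Ctss (3.51) and Cd74 (3.38), were under 4 on all pNCSC arrays. This argument is limited, because the same members were under 4 on the rNCSC arrays too. No array here shows that their probe sets respond, so silent probe sets cannot be told from absent cells. Expression of Cd14, Trem2 and Cd53 by the cultured cells themselves was not tested.

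Over the 10 splits of the 6 arrays into 3 and 3, a share under 0.05 cannot be reached. The real grouping gave 8596 changed genes and 5566 changed at least 2-fold, each the single split with as many (1 of 10), and the highest of the other splits gave 0 in both. For the gene lists, the real grouping called 15, the highest other split called 17, and 3 of the 10 splits called at least 15. Every other split puts arrays of both cultures on each side, so it still carries part of the difference between the cultures. That difference also widens the spread within its groups, which lowers its gene counts. The other splits are therefore no reference without a difference, and neither the gene counts nor the list count can be judged against them.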
